A study of Homo sapiens with 6 samples.

How the data were processed

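Total RNA of HCT116, an established human colorectal carcinoma cell line, was measured on 6 single-channel arrays, 3 from cells given a negative control hairpin and 3 from cells given a hairpin against BTF3. Per the labels, the hairpins were brought in with lentivirus at a multiplicity of infection of 10 for 16 h in medium with 20% serum, cells were harvested 72 h after transduction, and 1 µg of total RNA per sample was amplified and labelled with Cy5. The labels use the words knockdown and knock-out for the same cells, and knockdown is used here. They do not say whether the 3 replicates of a group were separate cultures, so each p-value of a single gene measures only the spread between these samples.

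Per the file headers, the deposited raw table held 1 raw intensity for each of 31741 probes on each array, the authors' p-value that the probe was detected, and a spot mark. Some raw intensities were below 0, so background had already been subtracted. The scanner, the image software and the detection model are not given in the sources used here. The authors' normalized intensity equalled the raw intensity multiplied by 1 factor per array, with a largest departure of 0.000418 on the log2 scale, and the deposited series values were the same numbers to within 5e-07. The factors were 1.04, 0.867 and 0.776 for controls 1 to 3 and 2.94, 0.904 and 0.870 for knockdown arrays 1 to 3. The authors also deposited a log2 ratio of knockdown over control and a p-value per probe, and tables of the probes they called, from a group model that the files do not describe. Of the deposited tables, a further copy of the called probes and a rounded copy of the normalized table were not used.

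Raw intensities were set to at least 1, log2 transformed and quantile normalized between arrays. A probe was kept when its detection p-value was under 0.05 on every array of at least 1 group. Of the probes, 25684 named a single gene, 1169 named several and 4888 named none, and the last kinds entered no gene-level test. Symbols were updated through the gene identifiers of the reference annotation for 25409 of the single-gene probes, and 275 kept the symbol of the file. A gene was represented by its kept probe with the highest mean log2 intensity, which left 14420 genes. For arrays, precision is limited by their number.

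The groups were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested. A gene was called at an adjusted p under 0.05. Errors are limma standard errors unless named SD. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists with at least 5 measured members. This test asks whether a list moves more than the other genes. At the preset correlation its p-value counts genes, not arrays, as replication, so it does not measure the spread between samples. Camera with an estimated correlation, where the degrees of freedom are limited by the arrays, and fry were run beside it. Fry is a rotation test of whether a list moves on balance in 1 direction, whatever the other genes do. Figures were drawn with matplotlib 3.10.9.

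Of 33 gene lists fixed from textbook knowledge before the data were examined, 32 had measured members. Before the data were examined, the filter, the normalization, the tests and the rule for named genes were also fixed. That rule takes every measured member of the nascent chain complex, the 12 largest rises and the 12 largest falls among called genes whose groups do not overlap and whose higher group was detected on every array, up to 4 called members per list with the smallest adjusted p, and CCN3, which a label names.

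The comparison of all 6 arrays called no gene, and knockdown array 1 stood apart from the other 5, so the same comparison was repeated without that array, on 15073 genes. This repeat, and the use of the rule for named genes on it, were chosen after the data were seen. On the 5 arrays the rule gave 134 genes. Among the named genes, 31 had over 1 kept probe, and for 10 of these the log2 fold changes of the probes differed in sign. Examples in the text were then limited to the 12 lists that camera called with 6 or with 5 arrays, to the ribosome-associated chaperones and to the ER unfolded protein response, also after the data were seen. The 79 genes followed through the alternatives were these examples, the genes with the largest changes, the complex, and called members of lists added later. A few of the genes so chosen are not reported here.

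Where a gene was detected on no array of its lower group, the fold is printed as a bound. It is the mean of the higher group minus the mean of the lower group, with each undetected value raised to the lowest value of any detected probe on its array.

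The alternatives were a replicate block, median, 75th percentile and cyclic loess scaling, the authors' normalized values, no filter and a filter on every array, the mean of a gene's probes, eBayes with trend and robust fitting, an unmoderated equal-variance test, other thresholds, and each array left out in turn. Added after the data were seen were 50 units added before log2, marked spots counted as undetected, 3 kinds of limma array weights, the log2 median raw intensity of each array as a covariate, the repeat of these settings without knockdown array 1 except for the replicate block and the array weights, and 6 further gene lists.

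The steps were tested on simulated data with noise of the size seen on these arrays, in 5 runs with 200 changed genes each. The noise was drawn independently for each gene and array. It held no correlation between genes and no trend shared by arrays, so the shares of false calls below do not cover either. With 6 arrays, 0% of changes of 1 and 8.4% of changes of 2 on the log2 scale were recovered. With 5 arrays these shares were 79.8% and 99.6%, and 0.086% of unchanged genes were called. Of lists shifted by 1, 25 of 25 were called with either number of arrays, against 1 and 0 of 125 unshifted lists.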

Results

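BTF3 is the beta subunit of the nascent polypeptide-associated complex, which binds new chains at the ribosome, and was first described as a transcription factor. The series asks which transcripts differ in HCT116 colorectal carcinoma cells when BTF3 is knocked down with a lentiviral hairpin. It holds 3 negative control and 3 knockdown samples, each on 1 array. The median raw intensity was 263, 298 and 395 units on controls 1 to 3 and 98, 326 and 351 units on knockdown arrays 1 to 3. Of 31741 probes, 68.1%, 68.1% and 73.7% were detected on the controls and 59.2%, 72.8% and 73.4% on the knockdown arrays. Across all probes, the log2 intensities of knockdown array 1 correlated with those of the other arrays at 0.853 to 0.893, and the other 5 arrays correlated with each other at 0.969 to 0.991. These correlations are across probes, which are not independent replicates. Marked spots numbered 5037 on knockdown array 1 and 2130 to 3050 on the others. Every value below is therefore given for all 6 arrays, or for the 5 arrays without knockdown array 1 (2 knockdown against 3 control), as stated.

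BTF3 itself was far lower in every knockdown sample. Its brighter probe read 30942, 30070 and 53000 raw units on controls 1 to 3 and 102, 1435 and 1457 units on knockdown arrays 1 to 3. After normalization these were 14.82, 14.54 and 15.41 against 8.13, 10.14 and 10.06 on the log2 scale. The log2 fold change was -5.48 ± 0.60 over 6 arrays (limma adjusted p = 0.145, rank 4 by p) and -4.66 ± 0.25 over 5 arrays, a 25.3-fold fall (adjusted p = 0.00127). A second BTF3 probe changed by -3.23 ± 0.25 over 5 arrays. Of the rest of the complex, the paralog BTF3L4 rose over 5 arrays, by 2.05 ± 0.16 (adjusted p = 0.00207), although its second probe changed by -0.26. NACA, the alpha subunit, changed by 0.25 ± 0.13 and was not called (adjusted p = 0.203), with single-gene probes between -0.06 and 0.87. The probe at 0.87 passed when adjusted over all probes (adjusted p = 0.0497). So did 1 of the 3 probes that NACA shares with NACA2, 2 of them also with NACAP1 (0.61, adjusted p = 0.0367). The list of 3 measured members had 1 rise and 1 fall both over all genes and adjusted over the list alone, too few for a set test. CCN3, which a label names, and NACAD were detected on no array.

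**Figure D1:**
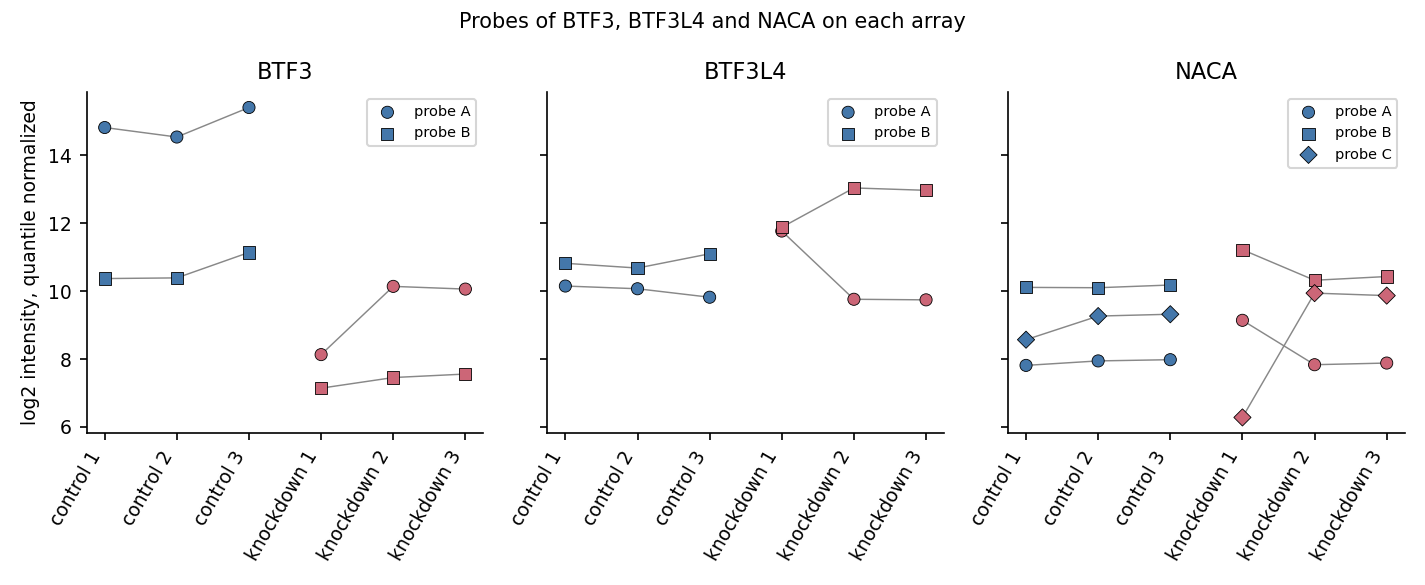
Each point is the quantile normalized log2 intensity (y axis) of 1 single-gene probe of BTF3, BTF3L4 or NACA on 1 array (x axis), blue for the 3 controls and red for the 3 knockdown arrays, with lines joining a probe's values within a group. The brighter BTF3 probe lies between 14.54 and 15.41 in the controls and between 8.13 and 10.14 in the knockdown arrays.

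Over 5 arrays the knockdown went with lower transcripts of DNA replication and mitosis and with higher transcripts of p53 target genes, and 3934 of 15073 genes were called by limma, 1757 higher and 2177 lower. With an estimated correlation 0 lists were called over 5 arrays (adjusted p = 0.0632 for S phase and replication, 0.0557 for G2 and mitosis and 0.19 for p53 targets). Of the called genes, 643 were higher and 753 lower by at least 1 on the log2 scale. Member counts of the lists below are to be read against the 1757 higher and 2177 lower of all 15073 genes. Over all 6 arrays limma called 0 of 14420 genes, with a smallest adjusted p of 0.145, while 1316 genes had an unadjusted p under 0.05 (384 higher and 932 lower) against 721 by chance. An unmoderated equal-variance test called 25 genes over 6 arrays and 292 over 5. The groups did not overlap for 3278 genes over 6 arrays (22.7%, where chance gives 10%) and for 9126 over 5 (60.5%, where chance gives 20%). The 5-array count moved to 1509 without control 1, 6310 without control 3, 707 without knockdown array 2 and 668 without knockdown array 3, where the lone knockdown array is assumed to vary like the controls. The median of all genes lay at 0.144 over 6 arrays with 75th percentile scaling and at -0.124 over 5 arrays with median scaling, and list medians under the scalings are given below relative to the median of all genes.

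The 12 largest rises over 5 arrays, leaving out LCE1C and SDCBP2, ran from 2.42 for CDKN1A to 3.39 for KCNC1 on the log2 scale. LCE1C, a cornified envelope protein, and SDCBP2 were detected on no control array, so their place among the 12 rests on control readings near background. LCE1C was at least 5.57-fold higher (adjusted p = 0.00127) and SDCBP2 at least 2.00-fold higher. Of the 12 genes, 8 lay below the control mean on knockdown array 1, among them MORF4L2 (-2.17), SERINC1 (-1.86), SERPINB5 (-1.16), ITGA2 (-0.94) and PROCR (-0.69). SERPINB5, the serpin maspin, rose by 2.54 ± 0.37 and ITGA2, the integrin alpha 2 chain, by 2.48 ± 0.34 (adjusted p = 0.00553 and 0.00508), with a second ITGA2 probe at 0.87. ANGPT2, an angiopoietin, rose by 2.70 ± 0.13, PROCR, the protein C receptor, by 2.53 ± 0.36, and CPA4, a carboxypeptidase, by 2.50 ± 0.14. CDKN1A, the cyclin-dependent kinase inhibitor induced by p53, rose by 2.42 ± 0.21, a 5.36-fold rise (adjusted p = 0.00219), and differed from the control mean by -1.57 on knockdown array 1. SERINC1 rose by 3.14 ± 0.42, CATSPERQ by 2.73 ± 0.16, MORF4L2 by 2.49 ± 0.52 and the potassium channel gene KCNC1 by 3.39 ± 0.98 (adjusted p = 0.0440). SERINC1 and KCNC1 were detected on 1 of 3 controls. KCNC1 was not called without control 1, control 3, knockdown array 2 or knockdown array 3 (adjusted p = 0.167, 0.0605, 0.379 and 0.0935), was 0.50 on the log2 scale without knockdown array 2, and had a second probe at -0.15. MORF4L2 was not called without control 1, control 2, knockdown array 2 or knockdown array 3 (adjusted p = 0.0810, 0.0539, 0.0757 and 0.0704).

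The 12 largest falls over 5 arrays ran from -4.66 for BTF3 to -2.26 for VOPP1. PHGDH, the first enzyme of serine synthesis, fell by 2.71 on the log2 scale (-2.71 ± 0.17, a 6.56-fold fall, adjusted p = 0.00127) and was also lower on knockdown array 1 (difference -5.17). TK1, the thymidine salvage kinase, changed by -2.36 ± 0.15 and FOXM1, a transcription factor of mitotic genes, by -2.32 ± 0.18 (adjusted p = 0.00127 and 0.00198). NFE2L1, a transcription factor of proteasome genes, changed by -2.34 ± 0.13, and FOXH1, a partner of SMAD proteins, by -2.53 ± 0.21. The protease inhibitor SLPI changed by -2.37 ± 0.21, the short-chain dehydrogenase DHRS2 by -2.66 ± 0.20 and the amino acid transporter SLC36A1 by -2.30 ± 0.22, although a second SLC36A1 probe changed by -0.12 and the mean of its probes by -1.21. NSMCE1, of a complex in chromosome maintenance, changed by -2.33 ± 0.16, and VOPP1 by -2.26 ± 0.19. CCDC175, detected on neither of knockdown arrays 2 and 3, was at least 3.44-fold lower, a rank that rests on readings near background, yet stood 2.84 above the control mean on knockdown array 1, where the other 11 of the 12 lay below it. Each of these falls passed limma at 5 arrays with an adjusted p of 0.00304 or less, and none was called over 6 arrays.

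**Figure D2:**
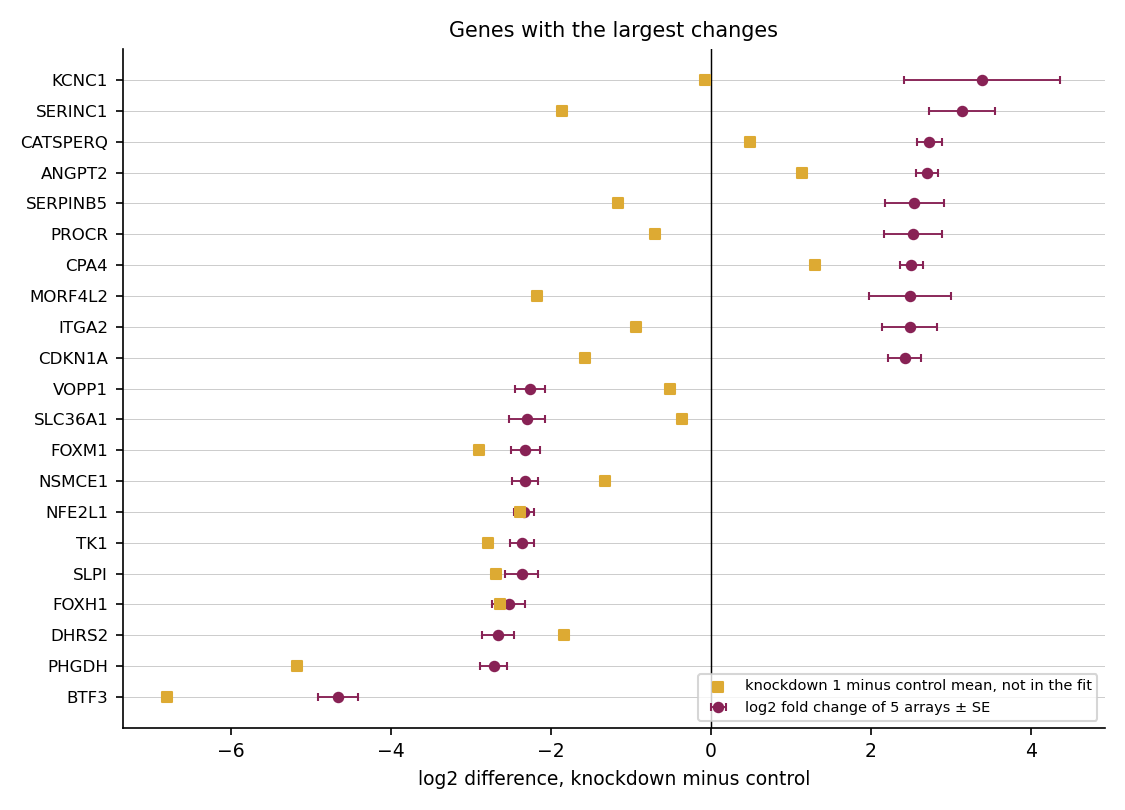
Circles give the log2 fold change of knockdown arrays 2 and 3 against 3 controls with its limma standard error (x axis) for BTF3 and the genes with the largest changes, leaving out those detected on no array of 1 group, and squares give knockdown array 1 minus the control mean. CDKN1A lies at 2.42 over 5 arrays and at -1.57 on array 1, while FOXM1 lies at -2.32 and -2.90.

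Cell cycle transcripts were lower over 5 arrays. Of 50 measured genes of S phase and replication, 36 fell, 2 rose and 12 were not called over 5 arrays (38 fell and 2 rose adjusted over the list alone), with a median log2 fold change of -1.01. Of 50 genes of G2 and mitosis, 38 fell, 0 rose and 12 were not called (42 fell adjusted over the list alone), with a median of -1.21. RRM2, the small subunit of ribonucleotide reductase, changed by -2.21 ± 0.14 with a second probe at -1.18, MCM3 of the replicative helicase by -1.66 ± 0.14 and CDC45 by -1.60 ± 0.13, although a second CDC45 probe changed by 0.58. CDC20, an activator of the anaphase-promoting complex, changed by -1.71 ± 0.14, the spindle protein gene ASPM by -1.63 ± 0.14 and the centromere chaperone gene HJURP by -1.43 ± 0.13. The adjusted p of each of these 6 genes was 0.00229 or less. The medians on knockdown arrays 1, 2 and 3 were -1.88, -1.02 and -1 for S phase and -1.73, -1.25 and -1.26 for G2 and mitosis, against -0.04 to 0.02 and -0.03 to 0.07 on the controls. Knockdown array 1 was low in other lists too, with medians of -1.5 for proteasome, -1.41 for ribosomal protein, -1.57 for MYC target, -1.75 for ATF4 and -1.13 for reference genes. On arrays 2 and 3 these were 0.219 and 0.202, 0.221 and 0.216, -0.305 and -0.303, -0.457 and -0.487, and -0.0751 and -0.119. Camera called both lists lower over 5 arrays (adjusted p = 2.02e-12 and 1.32e-16), and with an estimated correlation the adjusted p was 0.0632 and 0.0557. The fry test, which takes no preset correlation, called both over 5 arrays (adjusted p = 0.00112 for each). It does not weigh a list against other genes and called 14 of 31 lists there, so its calls do not make up for those of camera. Over 6 arrays the medians were -1.30 and -1.31, both lists were called (adjusted p = 2.28e-17 and 5.56e-23), and both stayed called with an estimated correlation (adjusted p = 0.00669 for each). Adjusted over the list alone, 17 of 49 and 20 of 50 members fell over 6 arrays, and 0 members were called over all genes, where limma called none. Relative to the median of all genes, the list medians lay between -1.34 and -0.941 over 5 scalings with either number of arrays. Of these scalings, 3 use 1 factor per array and so give the same value.

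Targets of p53 were higher over 5 arrays, and genes of the amino acid response were lower. Of 35 p53 target genes, 18 rose, 0 fell and 17 were not called (22 rose and 1 fell adjusted over the list alone), with a median of 0.625 and a camera adjusted p of 1.49e-07 (adjusted p = 0.19 with an estimated correlation). Beside CDKN1A, TP53I3 rose by 2.02 ± 0.14, TP53INP1 by 1.54 ± 0.16 and RRM2B, the p53-induced ribonucleotide reductase subunit, by 1.10 ± 0.13, each with an adjusted p of 0.00316 or less. The p53 list had a median of 0.690 and 0.638 on knockdown arrays 2 and 3 but 0.00847 on array 1, and 0.492 over 6 arrays (camera adjusted p = 0.000121, and adjusted p = 0.591 with an estimated correlation), where 3 members rose adjusted over the list alone. The 6-array median was 0.322 without control 1, 0.261 without knockdown array 2 and 0.269 without knockdown array 3. Of 31 genes of the ATF4 and amino acid response, 14 fell, 4 rose and 13 were not called over 5 arrays, the same counts adjusted over the list alone, with a median of -0.454 (camera adjusted p = 0.00991, and adjusted p = 0.26 with an estimated correlation). PHGDH belongs to this list. PCK2, a mitochondrial carboxykinase, changed by -2.22 ± 0.14 with a second probe at -1.33, the transcription factor gene CEBPG by -2.21 ± 0.17 and the cystine transporter gene SLC7A11 by -1.55 ± 0.14, each with an adjusted p of 0.00229 or less. Over 6 arrays the ATF4 median was -0.889 (camera adjusted p = 2.66e-06, and adjusted p = 0.591 with an estimated correlation), 7 members fell adjusted over the list alone, and the median on knockdown array 1 was -1.75 against -0.457 and -0.487 on the other knockdown arrays. Relative to all genes, the p53 median was 0.563 to 0.676 over 5 arrays and 0.309 to 0.475 over 6 across the 5 scalings. The ATF4 median was -0.478 to -0.402 and -0.947 to -0.855. Both lists were called in all of them.

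DNA repair genes were lower and immediate early genes higher over 5 arrays. Of 32 genes of DNA repair and damage signalling, 14 fell, 2 rose and 16 were not called (16 fell and 3 rose adjusted over the list alone), with a median of -0.468 (camera adjusted p = 0.00698, and adjusted p = 0.26 with an estimated correlation). RAD54L of homologous recombination changed by -1.71 ± 0.13, the mismatch repair gene MSH6 by -1.65 ± 0.16, MDC1 by -1.57 ± 0.13 and the histone gene H2AX by -1.87 ± 0.22, although a second H2AX probe changed by 0.11. Without control 3 as well, the list was not called (adjusted p = 0.0830, median -0.484). Over 6 arrays its median was -1.09 (camera adjusted p = 4.26e-07, and adjusted p = 0.125 with an estimated correlation), and 4 members fell adjusted over the list alone. The DNA repair median on knockdown arrays 1, 2 and 3 was -1.14, -0.562 and -0.533, where reference genes were at -1.13 on array 1. Of 29 immediate early genes, 11 rose, 4 fell and 14 were not called over 5 arrays (13 rose and 5 fell adjusted over the list alone), with a median of 0.431 (camera adjusted p = 0.00897, and adjusted p = 0.26 with an estimated correlation). DUSP2, a phosphatase of MAP kinases, rose by 1.23 ± 0.14 and the transcription factor gene EGR1 by 1.19 ± 0.16, while the factors KLF4 and KLF2 changed by -1.49 ± 0.15 and -1.36 ± 0.18. EGR1 was not called without knockdown array 2 (adjusted p = 0.0502). The immediate early list was not called over 6 arrays (median 0.153, camera adjusted p = 0.13), where 2 members rose and 1 fell adjusted over the list alone. Its median was -0.221 on knockdown array 1, against 0.407 and 0.327 on arrays 2 and 3. Relative to all genes, the DNA repair median was -0.509 to -0.408 over 5 arrays and -1.11 to -0.978 over 6 across the 5 scalings, called in all. The immediate early median was 0.452 to 0.486, called in all, and 0.0771 to 0.147, called in none.

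Ribosomal protein and respiratory chain genes were called higher over 5 arrays, with small medians. Of 70 cytosolic ribosomal protein genes, 13 rose, 6 fell and 51 were not called, the same counts adjusted over the list alone. Over all 15073 genes, 1757 rose and 2177 fell. The ribosomal median was 0.209 (camera adjusted p = 0.00487, and adjusted p = 0.26 with an estimated correlation). RPS19 rose by 1.36 ± 0.20 and RPS10 by 1.03 ± 0.14, while RPL32 changed by -1.25 ± 0.19 and RPL9 by -2.00 ± 0.20, with a second RPL9 probe at 1.39. Of 69 oxidative phosphorylation genes, 18 rose, 4 fell and 47 were not called (19 rose and 4 fell adjusted over the list alone), with a median of 0.224 (camera adjusted p = 0.00487, and adjusted p = 0.305 with an estimated correlation). NDUFB4 of complex I rose by 1.42 ± 0.15 and UQCR10 by 1.06 ± 0.14, while the succinate dehydrogenase subunit gene SDHC changed by -1.40 ± 0.16, with a second probe at -0.26 and a mean of probes of -0.83. Relative to all genes, the medians were 0.141 to 0.317 for ribosomal proteins and 0.129 to 0.296 for oxidative phosphorylation over 5 scalings, and each list was called with 2 of the 5. Over 6 arrays neither was called (medians -0.41 and -0.0246, camera adjusted p = 0.342 and 0.48). There the oxidative phosphorylation median relative to all genes was -0.0681 to 0.05 over 5 scalings, above 0 with cyclic loess alone, and the ribosomal median was -1.41 on knockdown array 1 against 0.221 and 0.216 on arrays 2 and 3. No member of either list was called over 6 arrays, adjusted over the list alone or over all genes. Without knockdown array 2 the adjusted p was 0.0621 for RPS10, 0.0547 for RPS19, 0.0535 for RPL32 and 0.0589 for UQCR10, and without knockdown array 3 it was 0.0519 for RPL32.

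Of 30 genes of ribosome-associated chaperones and targeting, 3 rose and 2 fell over 5 arrays, the same counts adjusted over the list alone (camera adjusted p = 0.848). The prefoldin subunit genes PFDN6 and PFDN2 rose by 0.72 ± 0.14 and 0.63 ± 0.14, while PFDN1 changed by -0.72 ± 0.13 and NAA15, a subunit of an acetyltransferase bound to ribosomes, by -0.76 ± 0.14. These 4 genes were not called without knockdown array 2 (adjusted p = 0.129, 0.152, 0.116 and 0.0886) or without knockdown array 3 (adjusted p = 0.111, 0.159, 0.0899 and 0.111), nor were PFDN6 and PFDN2 without control 1 (adjusted p = 0.0587 and 0.0653). Of 23 genes of the ER unfolded protein response, 7 fell and 3 rose (7 fell and 4 rose adjusted over the list alone), with a camera adjusted p of 0.439 and a fry adjusted p of 0.0189. MANF, a secreted ER protein, changed by -1.21 ± 0.15 and the ER chaperone gene HSPA5 by -1.05 ± 0.15. The disulfide isomerase gene PDIA4 changed by -0.90 ± 0.14, and PDIA3, whose probe was detected on no knockdown array of the 5, was at least 1.74-fold lower. HSPA5 was not called without knockdown array 3 (adjusted p = 0.0600), and PDIA3 and PDIA4 were not called without knockdown array 2 (adjusted p = 0.0560 and 0.0686) or without knockdown array 3 (adjusted p = 0.0863 and 0.0734).

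Over 6 arrays camera called 9 of 31 lists, 2 higher and 7 lower, and 4 of the 9 were not called over 5 arrays. These were MYC target genes (6-array median -0.60, camera adjusted p = 1.69e-05, and adjusted p = 0.665 with an estimated correlation), cholesterol synthesis (-0.333, 0.0476 and 0.665), leukocyte markers (0.446, 0.03 and 0.686) and reference genes (-0.486, 0.0476 and 0.665). Their medians on knockdown array 1 were -1.57, -1.19, 1.35 and -1.13, and over 5 arrays they were -0.342, 0.0253, -0.0432 and -0.0878 (camera adjusted p = 0.152, 0.886, 0.983 and 0.983). Over 6 arrays cholesterol synthesis was called with 2 of 5 scalings and reference genes with 1 of 5, and over 5 arrays MYC targets were called with 2 of 5 (lowest adjusted p = 0.0247). With control 3 left out of the 6 arrays instead, cholesterol synthesis and reference genes were not called either (adjusted p = 0.14 and 0.114). With knockdown array 2 left out the medians were -0.521 for cholesterol synthesis, 0.769 for leukocyte markers and -0.773 for reference genes, and with knockdown array 3 left out they were 0.688 for leukocyte markers and -0.777 for reference genes. Over 5 arrays, 12 MYC targets fell and 5 rose of 45 (15 and 5 adjusted over the list alone), among them UTP20 at -1.38 ± 0.16 and NOP56 at 1.15 ± 0.17 (second probe 1.95), which act in ribosome assembly. In cholesterol synthesis 6 fell and 3 rose of 25 (7 and 4 adjusted over the list alone), among them the sterol reductase genes DHCR7 at -0.95 ± 0.14 and TM7SF2 at 1.02 ± 0.14. Of 15 reference genes 3 fell and 2 rose, the same adjusted over the list alone, among them the tubulin gene TUBB at -1.20 ± 0.13. Of 10 leukocyte markers, CD68 rose by 1.11 ± 0.26 and ITGAM changed by -0.70 ± 0.15, the same counts adjusted over the list alone. NOP56 was not called without knockdown array 3 (adjusted p = 0.0598), TM7SF2 without array 2 (adjusted p = 0.0597), DHCR7 without array 2 or array 3 (adjusted p = 0.0547 and 0.0752), ITGAM without control 1, knockdown array 2 or array 3 (adjusted p = 0.0659, 0.151 and 0.118), and CD68 without the same arrays (adjusted p = 0.0655, 0.0795 and 0.152). Of the other markers of foreign cells, the medians on knockdown array 1 were 0.532 for fibroblast, 1.08 for endothelial and 1.31 for packaging line genes. On arrays 2 and 3 they were -0.497 and -0.5, 0.111 and -0.197, and -0.295 and -0.334. Other lists were also high on array 1, at 0.768 for replication-dependent histones, 0.702 for NF-kB and 0.668 for mesenchymal transition genes, while reference genes were at -1.13. These markers therefore do not single out foreign cells there.

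**Figure D3:**
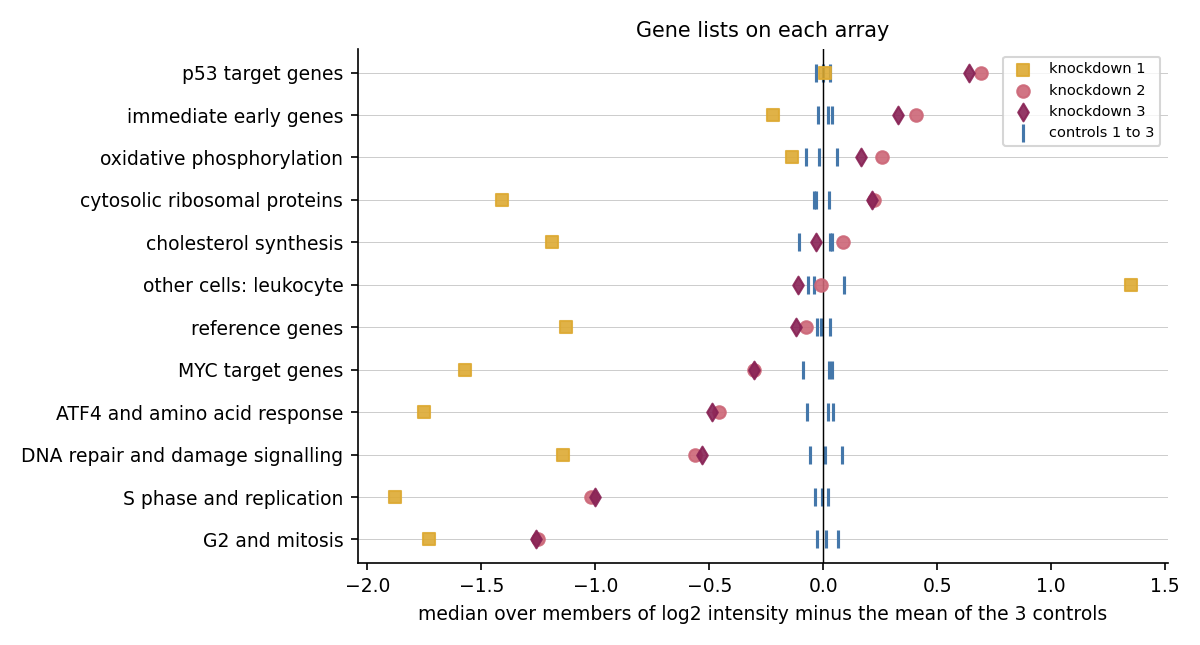
For each gene list that camera called with 6 or with 5 arrays, marks give the median over its members of the quantile normalized log2 intensity minus the mean of the 3 controls (x axis), as blue ticks for the controls and as coloured symbols for knockdown arrays 1 to 3. Arrays 2 and 3 lie close together in every list, and array 1 lies apart from them, at 1.35 against -0.00992 and -0.111 for leukocyte markers.

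The remaining lists were not called by camera over 5 arrays. Heat shock genes had 3 rises and 1 fall of 17 (adjusted p = 0.0683), proteasome genes 6 and 1 of 33 (adjusted p = 0.0683) and JAK-STAT signalling 10 and 2 of 30 (adjusted p = 0.0683). Hypoxia and glycolysis had 6 rises and 3 falls of 35 (adjusted p = 0.177), apoptosis regulators 9 and 4 of 41 (adjusted p = 0.216) and RNA polymerase II with general factors 11 and 5 of 39 (adjusted p = 0.492). Interferon-stimulated genes had 7 rises and 7 falls of 36 (adjusted p = 0.901), NF-kB and inflammatory genes 1 and 3 of 24 (adjusted p = 0.439), Wnt targets 2 and 1 of 20 (adjusted p = 0.901) and NRF2 genes 3 and 5 of 24 (adjusted p = 0.688). Epithelial junction genes had 3 rises and 5 falls of 33 (adjusted p = 0.886), mesenchymal transition genes 4 and 2 of 34 (adjusted p = 0.983), integrins and matrix 5 and 6 of 34 (adjusted p = 0.886) and replication-dependent histones 4 and 3 of 13 (adjusted p = 0.688). Markers of other cells had 0 rises and 2 falls of 6 for fibroblast (adjusted p = 0.517), 1 and 1 of 7 for endothelial cells (adjusted p = 0.859) and 0 and 2 of 8 for packaging line genes (adjusted p = 0.177). Adjusted over the list alone, the counts were the same except for interferon-stimulated genes (8 and 8), apoptosis regulators (9 and 5), mesenchymal transition (3 and 2), integrins (6 and 6), JAK-STAT (11 and 3), RNA polymerase II (12 and 5) and fibroblast markers (1 and 4). No probe of the mitochondrial-encoded list was kept. Over 5 arrays camera called 8 of 31 lists, 4 higher and 4 lower, and 0 with an estimated correlation, while fry called 14. Over 6 arrays 2 lists were called with an estimated correlation and 2 with fry, S phase and G2 in both.

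The authors' deposited tables listed 325 probes as higher and 649 as lower in the knockdown, and gave BTF3 a log2 ratio of -5.01 with p = 9.27e-13. Over 5 arrays, 206 of the 269 tested genes they listed as higher rose and 489 of the 551 they listed as lower fell, against 31.4 and 79.6 expected by chance, and 10 genes were called in opposite directions. Over 6 arrays the shared count was 0 because limma called no gene, and at an unadjusted p under 0.05 with a change of at least 1 on the log2 scale 142 and 460 were shared, against 3 and 21.6 expected. These overlaps come from the same arrays and are not independent evidence.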

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

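The alternatives with array weights, with array brightness as a covariate, with 50 units added, with marked spots as undetected and all repeats without knockdown array 1 were chosen after the data were seen. Deviations from the group mean correlated across genes at 0.42, -0.275 and 0.476 for arrays of the same replicate number. For arrays of different numbers the range was -0.521 to 0.529. Deviations within a group cancel out for each gene, and knockdown array 1 stood far apart. The deviations of the other knockdown arrays therefore largely mirror those of array 1. For this reason the check cannot decide whether the replicate numbers pair the arrays. With the replicate block limma called 0 genes over 6 arrays and BTF3 had an adjusted p of 0.63, its highest under any setting that kept all 6 arrays. Planned settings not run were other background corrections (the values hold no background column), the series values (the same numbers as the authors' normalized values) and a slide or scan block (none is given). The cell cycle lists kept their direction and call in every setting run over 6 arrays, with medians from -1.37 to -1.01 for S phase and from -1.32 to -1.21 for G2 and mitosis when 1 array was left out. BTF3 stayed called in every setting run over 5 arrays. Signal over background limits detection on the dimmest array, where 59.2% of probes were detected, but its departure from the other arrays was not confined to dim probes.

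The count of changed genes depends on how knockdown array 1 is treated. Over 6 arrays it was 0, with 1316 genes at an unadjusted p under 0.05. It was 25 with the unmoderated test, 738 at an unadjusted p under 0.05 with a change of at least 1, and 0 to 3934 with 1 array left out, where 3934 came without knockdown array 1 and 0 without any other array. With that array kept but weighted, the count was 6865 with limma weights gene by gene, where its weight was 0.0244. These weights were 4.86 and 3.98 for knockdown arrays 2 and 3 and 0.718 for control 3. The count was 6113 with REML weights, which did not converge and gave knockdown array 2 a weight of 0.00647. It was 7378 with REML weights and a prior of 100 genes. With the brightness covariate the count was 3465. That fit passes almost through knockdown array 1 (leverage 0.946), so the array adds little to the residual spread. BTF3 was called in these 4 settings, with log2 fold changes of -4.75, -4.81, -4.79 and -4.94, and ranged from -5.88 to -4.66 with 1 array left out. The genes shared with the authors' calls numbered 602 at an unadjusted p under 0.05 with a change of at least 1, and 695 without knockdown array 1.

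Over 5 arrays the count of 3934 became 292 with the unmoderated test, 1148 at an adjusted p under 0.01, 1396 with a change of at least 1, and 1439 at an unadjusted p under 0.05 with a change of at least 1. With a further array left out it was 1509 without control 1, 6310 without control 3, 707 without knockdown array 2 and 668 without knockdown array 3, a range of 668 to 6310, where fewer arrays lower the precision and a lone knockdown array is assumed to vary like the controls. The count rose without control 3, the control that correlated most with knockdown arrays 2 and 3 (0.982 and 0.980). Of the 79 genes followed, 52 lost their call with the unmoderated test, 26 without knockdown array 2 and 22 without knockdown array 3, and none changed direction over 5 arrays. With the mean of a gene's probes RPL9 (-0.30), CDC45 (-0.51), KCNC1 (1.62) and ALDH1L2 (-0.32) were not called (adjusted p = 0.136, 0.125, 0.0692 and 0.172). With the same setting BTF3L4 (0.89), SLC36A1 (-1.21), SDHC (-0.83), H2AX (-0.88) and ATG7 (-0.62) moved by over 1.5 times and stayed called (adjusted p = 0.00518, 0.00374, 0.00695, 0.0149 and 0.0284). PFDN2 was not called with median scaling (0.40, adjusted p = 0.14) or 75th percentile scaling (0.47, adjusted p = 0.0727). KCNC1 was not called without a filter (adjusted p = 0.0708) or with the brightness covariate (adjusted p = 0.0564).

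The lists called over 6 arrays numbered 2 with an estimated correlation and 2 with fry, and over 5 arrays 0 and 14. With an estimated correlation over 5 arrays, S phase kept its median of -1.01 (camera adjusted p = 0.0632) and G2 and mitosis its median of -1.21 (camera adjusted p = 0.0557). Neither was called, although the estimates, 0.0057 and -0.012, lay below the preset 0.01. A higher correlation is therefore not what ended the calls. For these lists the other difference is in the degrees of freedom, taken from the genes with the preset correlation and from the arrays with the estimated one. The fry test, which does not weigh a list against other genes, called both (adjusted p = 0.00112 for each). Cholesterol synthesis changed the direction of its test over 6 arrays with the 3 kinds of weights (medians -0.0196, -0.104 and -0.0812, in the order above), and leukocyte markers with both REML weights (medians -0.121 and -0.112).

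Single genes that limma did not call over 6 arrays changed sign in these settings. With gene by gene weights, REML weights, REML weights with the prior and the covariate, in this order, PFDN6 was 0.78, 0.73, 0.75 and 0.57, PFDN2 was 0.69, 0.68, 0.69 and 0.41, NOP56 was 1.27, 1.34, 1.34 and 0.88, and ITGAM was -0.67, -0.59, -0.62 and -0.40. These 4 genes were called with each of the weights (adjusted p of 0.0298 or less) and not with the covariate (adjusted p = 0.0605, 0.262, 0.0501 and 0.29). KCNC1 was -0.32 with gene by gene weights and -0.10 with the covariate. NOP56 was 0.20 with the mean of its probes. With median scaling UQCR10 was -0.19 and TM7SF2 -0.045, and with the authors' values UQCR10 was -0.11. These scalings use 1 factor per array and differ from quantile normalization by more than a shift of all genes alike. The median of all genes over 6 arrays was 0.017 with quantile normalization, -0.058 with median scaling and 0.0286 with the authors' values. With 1 array left out, KCNC1 ranged from -0.044 to 3.39, CCDC175 from -2.38 to 0.38, PFDN6 from -0.46 to 0.72, PFDN2 from -0.85 to 0.63, NOP56 from -0.91 to 1.15, NDUFB4 from -0.25 to 1.42, UQCR10 from -0.42 to 1.06, TM7SF2 from -0.18 to 1.02, DHCR7 from -0.95 to 0.027, KLF2 from -1.36 to 0.070 and ITGAM from -0.70 to 1.03. The cause of these changes of sign was not tested gene by gene.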

Other observations

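The 6 gene lists of the first paragraphs were chosen after the data were seen, so their direction is not independent evidence. The tests of a brightness trend shared with the controls, of the same change on knockdown array 1, of array brightness and the control trend as sources of the calls over 5 arrays, of the control trend in the cell cycle lists, and of other splits of the arrays were also chosen only after the result was seen. Genes of serine and one-carbon synthesis were lower over 5 arrays: 8 of 12 fell and 0 rose (8 fell and 1 rose adjusted over the list alone), with a median log2 fold change of -0.724 (camera adjusted p = 0.0125 over the 6 lists, and adjusted p = 0.273 with an estimated correlation). Beside PHGDH, the mitochondrial folate enzyme gene MTHFD2 changed by -0.82 ± 0.13. ALDH1L2, which oxidizes formyl folate, changed by -0.81 ± 0.16 and TYMS, thymidylate synthase, by -0.99 ± 0.17. PHGDH, MTHFD2 and ALDH1L2 also belong to the ATF4 list and TYMS to the S phase list, so the result is not separate from those lists. With the mean of its probes ALDH1L2 changed by -0.32 and was not called (limma adjusted p = 0.172). MTHFD2, ALDH1L2 and TYMS were not called without knockdown array 2 (adjusted p = 0.0929, 0.117 and 0.0744) or knockdown array 3 (adjusted p = 0.0717, 0.0833 and 0.0721), nor was ALDH1L2 without control 1 (adjusted p = 0.0528). Over 6 arrays the median was -0.992 (camera adjusted p = 0.000175, and adjusted p = 0.467 with an estimated correlation).

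Genes of autophagy and the lysosome were higher over 5 arrays: 13 of 32 rose, 2 fell and 17 were not called (14 rose and 3 fell adjusted over the list alone), with a median of 0.39 (camera adjusted p = 0.00104, and adjusted p = 0.273 with an estimated correlation). GABARAPL2, which coats autophagosomes, rose by 1.26 ± 0.17 and the cargo receptor gene SQSTM1 by 1.22 ± 0.17, while ATG7, an enzyme of autophagosome formation, changed by -1.33 ± 0.17, or by -0.62 with the mean of its probes (adjusted p = 0.0284). SQSTM1 was not called without knockdown array 2 (adjusted p = 0.0524), and the list was not called over 6 arrays (median 0.168, camera adjusted p = 0.185). Relative to all genes, the 5-array medians lay between -0.692 and -0.673 for serine and one-carbon synthesis and between 0.4 and 0.441 for autophagy and the lysosome over 5 scalings, and each was called in all 5. The other lists were not called over 5 arrays: squamous epithelium genes had 7 rises and 2 falls of 22 (adjusted p = 0.0695), translation initiation factors 7 and 2 of 28 (adjusted p = 0.076), mitochondrial ribosomal proteins 10 and 11 of 68 (adjusted p = 0.216) and aminoacyl-tRNA synthetases 2 and 3 of 20 (adjusted p = 0.775). Over 6 arrays squamous genes were called higher (median 0.465, adjusted p = 0.00404) and aminoacyl-tRNA synthetases lower (median -0.693, adjusted p = 0.0237), with an adjusted p of 0.467 and 0.578 with an estimated correlation.

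Knockdown array 1 stood apart from the other 5 arrays in brightness and in its profile. Noise of dim probes near background is argued against, because the spread of array 1 about knockdown arrays 2 and 3, over the spread between those 2 arrays, was 6.64 among the 7935 brightest probes and 1.68 among the 7936 dimmest. Over 4345 genes unmoved on knockdown array 3 the spread about the control mean was 6.23 times as large on array 1 as on array 2 (SD 1.42 and 0.228). The small SD on array 2 follows in part from the choice of genes, because arrays 2 and 3 correlated at 0.991. A response that only scales up the changes of array 3 is argued against as the whole of the departure. The test cannot tell a stronger response that moves further genes from added noise on array 1, so a stronger response stays open. The departure of array 1 from the other knockdown arrays correlated across genes at -0.521 with the departure of the brightest control from the other controls, so a trend with array brightness that the controls share may account for part of it. No cause of the low brightness, such as RNA quality or labelling, was tested, and BTF3 was lowest on this array.

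The cell cycle lists were lower on knockdown arrays 2 and 3, and on array 1, where other lists were low as well (-1.5 for proteasome genes, against 0.219 and 0.202 on arrays 2 and 3, and -1.13 for reference genes, against -0.0751 and -0.119). Array brightness as the whole cause is argued against over 5 arrays mainly by near-equal group means (log2 8.29 in the controls and 8.40 in the knockdown arrays). With brightness as a covariate the higher of the list medians was still -1.04 there, but a covariate so even between the groups could move little. The trend that sets the brightest control apart from the other controls is argued against too as the whole cause, with -1.06 once each array's score on it was the covariate. The choice of scaling is argued against by quantile normalization and cyclic loess. With these the highest of the list medians relative to all genes was -0.941 over 5 arrays and -1.18 over 6. The other 3 scalings use 1 factor per array and cannot differ among themselves. A candidate explanation that stays open as a hypothesis is fewer cycling cells after the loss of BTF3, beside an off-target effect of the hairpin or a difference in culture density, which the design cannot separate. This hypothesis was found and tested on the same arrays, and neither list was called by camera over 5 arrays with an estimated correlation (adjusted p = 0.0632 and 0.0557). The fry test, which called both (adjusted p = 0.00112 for each), does not weigh a list against other genes. A second hairpin, a rescue with resistant BTF3 or a cell cycle assay at matched density, which would decide the hypothesis, are not among these data.

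The 3934 genes called without knockdown array 1 rest on 2 knockdown arrays. Whether the same change was present on array 1 stays open. Of these genes, 45.6% had the same sign there (r = -0.092 over all genes), against 53.2% (52.1% to 54.9%) simulated with no change, independent noise and the same shared controls. Of those that rose, 32.6% were higher on array 1, and of those that fell, 56.1% were lower, where 46.5% of all genes were lower. The share varied when control 1, 2 or 3 was kept out of the fit and compared with array 1 alone. Then 57.7%, 52.8% and 33.0% of the genes called had the same sign there, against 49.4%, 49.7% and 49.6% expected from the shares of either sign. Array brightness as the whole source of the 3934 calls is argued against mainly by the near-equal mean log2 brightness over 5 arrays, 8.29 in the controls and 8.40 in the knockdown arrays. With brightness as a covariate 92.7% of the 3934 genes were called in the same direction, but a covariate so even between the groups could remove few calls. The trend that sets control 3, the brightest, apart from the other controls stays open as a source of part of them: knockdown arrays 2 and 3 minus control 1 correlated at 0.387 with control 3 minus control 2, their profiles correlated with control 3 at 0.982 and 0.980 against 0.969 to 0.970 with the other controls, and 61.8% were called in the same direction with each array's score on that trend as a covariate. Of the 10 splits of the 5 arrays into groups of 2 and 3, 1 gave as many genes, the real one, with 0 genes in the highest of the others, and all 10 splits of the 6 arrays gave as many as the real count of 0 (highest other 0), but with 10 splits a share under 0.05 cannot be had.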
